A study of Pleurotus ostreatus with 53 samples.

How the data were processed

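Each of 6 groups of Pleurotus ostreatus samples had 3 biological replicates, per the series description: mycelium of the monokaryons PC15 and PC9, mycelium of HyB, the dikaryon from mating PC9 and PC15, and mycelium, primordium and fruitbody of the N001 dikaryon. HyB carries the label N001_HyB, so both dikaryons bear the N001 name. The 53 libraries comprised 18 of mRNA, 18 of small RNA and 17 of bisulfite-treated DNA. Every value column was matched to a labelled library by group and replicate number. RNA was isolated with a fungal RNA kit and DNA with a fungal DNA kit, and libraries were made with an Illumina TruSeq kit, per the labels' protocols. The labels name FastQC and STAR for mRNA and FastQC and BS-Seeker2 for bisulfite data, per the submitters' processing notes. For small RNA no tool is given in the sources used here. The genome build, the counting program, its strand setting and the treatment of reads with several matches are also not given in the sources used here, so reads shared between similar, nested or overlapping copies could not be told apart.

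Gene mRNA values were deposited as RPKM, reads per kb of gene scaled to the mapped reads of the library, per the file headers. TE mRNA values and both sets of small RNA values were deposited as read counts, per the file headers. Methylation was deposited as a fraction from 0 to 1 for each gene or TE copy in the CG context, per the file headers, and was multiplied to percent here. The coverage behind each methylation level is unknown, so no interval or limit is given for it. The RPKM values turned out to be whole reads scaled by gene length and a library total: 94.3% to 95.8% of values per library were whole within 0.01 reads. This gave totals of 19628882 to 30123559 reads per mRNA library, of which 80.2% to 87.4% lay in genes. TE mRNA values in RPM, reads scaled to the library total, refer to these totals. Small RNA RPM refer to the sum of gene and TE reads, 191411 to 5746479 per library. In mRNA, HyB replicates 2 and 3 and primordium replicates 2 and 3 differed by little over sampling noise (chi-square per degree of freedom of 3.77 and 1.56, against 25.7 to 515 in the other pairs of a group), and were kept as separate replicates. Intervals and floors cover counting error only. The methylation table writes the names of HELPO1 families with a comma, which was read as a point, since the coordinates were those of the copies named with a point elsewhere.

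The comparisons, tests, thresholds and the rule for naming features were chosen before the data were examined. The 5 comparisons were PC9 against PC15, HyB against the mean of both monokaryons, N001 mycelium against HyB, primordium against mycelium, and fruitbody against primordium. Each table was fitted with all 6 groups and no other term. Gene mRNA was tested by limma-trend (limma 3.58.1, R 4.3.3) on log2 of RPKM plus 1, for genes with an RPKM of at least 1 in at least 3 libraries. Counts were tested by edgeR's quasi-likelihood test (edgeR 4.0.16) with TMM scaling and its default filter by expression. Methylation was tested by limma-trend on percentage points, for 11140 genes and 715 TE copies with a value in every library. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05, and tests were two-sided. Because TE copies took very different shares of the libraries, splits scaled by library totals are given beside those scaled by TMM wherever at least 10 copies or genes were called.

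Mean levels and shares per library were compared by exact two-sided permutation tests, adjusted over the 5 comparisons. For 3 against 3 libraries the smallest p is 0.1. Correlations across TE copies within a group used 100000 permutations and were adjusted over 18 correlations. TE classes with at least 5 tested members were tested by camera with a preset correlation of 0.01, by camera with an estimated correlation, and by fry. No camera call named in the text held with the estimated correlation. Named features were, for each TE table and comparison, up to 3 copies with the largest rise and 3 with the largest fall, past the threshold and with libraries that did not overlap. For TE mRNA and TE small RNA, overlap was judged on reads with TMM scaling inside the TE table. On reads scaled to library totals, 5 copies chosen for HyB against its parents did overlap, among them Copia_7 on scaffold 2 and Copia_5 on scaffold 7. For gene mRNA they were the 2 gene numbers with the largest rise and the 2 with the largest fall. TE families given as totals were chosen after their values were seen. None of the gene numbers matched the 11849 genes of the RefSeq table of a PC9 assembly, so that 0 genes could be named and the gene lists prepared before the data were examined were not used.

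Each test was run on simulated data for N001 mycelium against HyB, with known changes. The spread between replicates was set by hand, not estimated from these libraries, and replicates were drawn independently. The shares below therefore hold for that spread alone, and the real libraries may be noisier or less independent. Recovered were 23 of 100 genes changed 2-fold and 93 of 100 changed 4-fold for mRNA (10808 genes). For TE mRNA, 0 of 37 and 12 of 36 copies were recovered (286 copies). For gene small RNA, 1 of 100 and 10 of 100 genes were recovered (6740 genes), and for TE small RNA, 8 of 85 and 38 of 84 copies (616 copies). For methylation changes of 10 and 20 points, 94 of 94 and 93 of 93 genes were recovered (11140 genes), and 72 of 100 and 100 of 100 TE copies (715 copies). Of the calls in these simulated tables, the false share was 7.9% for mRNA genes (10 of 10610 unchanged genes called), 15.4% for small RNA genes (2 of 6540), 4.6% for gene methylation and 4.4% for TE methylation, and 0 for TE mRNA and TE small RNA. In this comparison, changes of up to 4-fold in small RNA and TE mRNA may therefore be missed. Recovery was not simulated for the other comparisons.

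Alternatives were other normalizations (quantile for RPKM, DESeq2 1.42.0 for counts), no filter on low values, a pseudocount of 0.1, a logit scale and a minimum mean level of 1% for methylation, the replicate number as a block, and leaving out each library in turn. Further alternatives were chosen after seeing the data: edgeR on the recovered reads, scaling by library totals, replicate 1 as a batch or left out of every group, nearly identical libraries merged, TE copies of at least 200 bp, every copy with a value, levels per kb of copy, and genes near TE copies with a methylation value in every library. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9.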

Results

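Mycelium and fruiting stages of the oyster mushroom Pleurotus ostreatus were profiled in 6 groups by mRNA sequencing, small RNA sequencing and bisulfite sequencing. PC15 and PC9 are monokaryons, with a single kind of nucleus per cell, and were sampled as mycelium. HyB, labelled N001_HyB, is the dikaryon made by mating PC9 with PC15, sampled as mycelium. The N001 dikaryon was sampled as mycelium, as primordium (the young fruiting initial) and as fruitbody. Each group had 3 libraries per assay, except primordium bisulfite sequencing with 2, which made 53 libraries. The mRNA libraries held 19628882 to 30123559 reads, and TE copies held 26671 to 422440 of them. Small RNA libraries held 191411 to 5746479 reads in genes and TE copies. The tables list 1051 copies of transposable elements (TEs) in 79 families: 792 Gypsy, 145 Copia, 40 LINE, 35 DIRS, 29 HELPO (Helitron) and 10 TIR copies. Gypsy and Copia are retrotransposons with long terminal repeats, and TIR elements are DNA transposons with terminal inverted repeats. Genes are known here by number only, so gene functions are not given. Errors are SD over 3 libraries unless another n is stated, and methylation is the CG level of a whole gene or TE copy.

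TE copies differed from genes in methylation and mRNA in every group. The median TE copy was methylated at 22.9% ± 0.417 in PC15 and 56.8% ± 2.48 (n = 2) in primordia, the lowest and highest group medians. The median gene was methylated at 0.229% ± 0.0142 in PC15 and 0.234% ± 0.0191 (n = 2) in primordia. TE copies had the higher median methylation in each of the 17 bisulfite libraries, and genes had the higher median mRNA level in each of the 18 mRNA libraries. Median small RNA showed no such rule: TE copies stood above genes in 3 of 3 fruitbody libraries, level with them in primordia, and below them in every PC15 and N001 mycelium library. Small RNA was not scaled by length here, whereas mRNA was. In each primordium library both medians fell on the same low read count. The TE means on the log2 scale were higher there, with 3.80 against 3.46, 3.45 against 2.78 and 3.42 against 2.74 in replicates 1, 2 and 3.

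**Figure D1:**
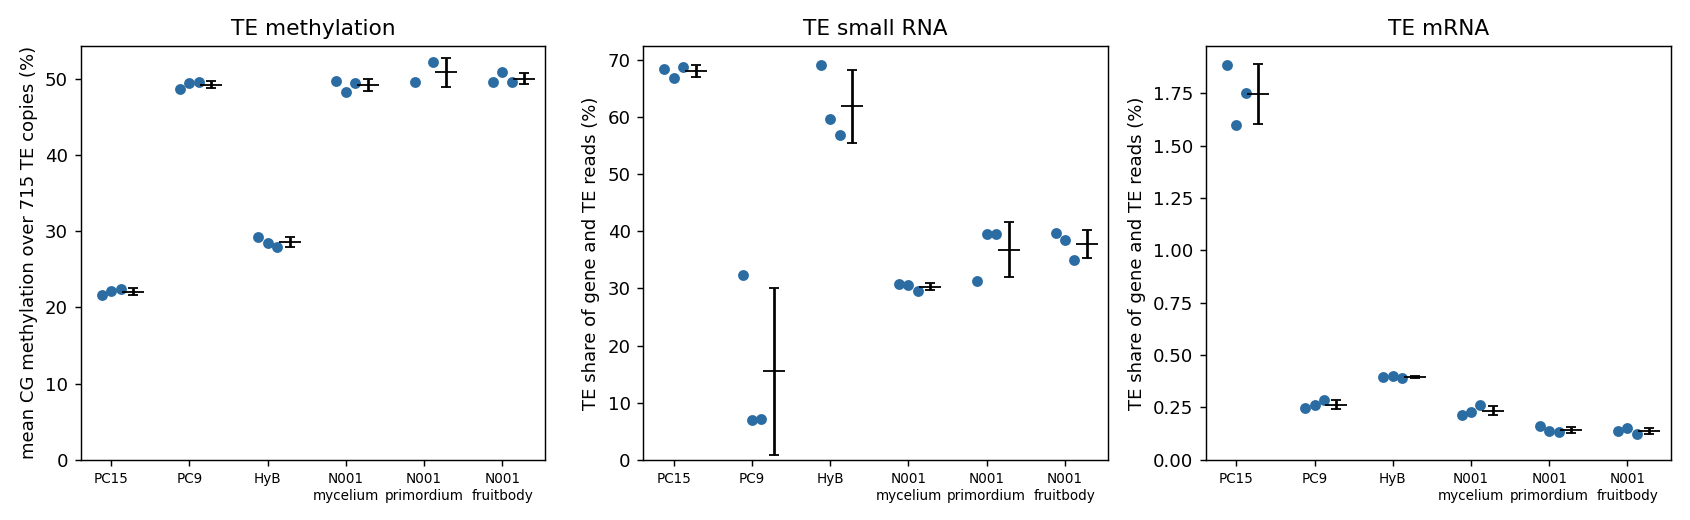
TE methylation (mean CG level over 715 TE copies, percent), TE share of small RNA reads (percent) and TE share of mRNA reads (percent) in each library of the 6 groups; points are libraries and bars are the mean with its SD. PC15 and HyB lie at 22.1% and 28.5% methylation, and the other 4 groups at 49.1% to 50.9%.

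The PC9 and PC15 comparison asks how far the parental strains differ in TE silencing. The listed TE copies were more methylated and held fewer mRNA reads in PC9 than in PC15. Of the listed copies, 977 had a methylation value in PC15 and 719 in PC9, so PC9 may be covered less well. Mean TE methylation was 49.2% ± 0.486 in PC9 and 22.1% ± 0.437 in PC15. TE copies took 2299.7 ± 178 mRNA RPM (reads scaled to the library total) in PC9 and 14642 ± 912 in PC15, a ratio of 0.157. They took 15.5% ± 14.6 of gene and TE small RNA reads in PC9 and 68.0% ± 1.04 in PC15. The PC9 share was 32.3% in replicate 1, against 6.93% and 7.17% in replicates 2 and 3. No library of either strain overlapped the other strain in these 3 measures. The exact two-sided permutation test gave p = 0.1 for each, the smallest that 3 against 3 libraries allow (adjusted p = 0.25 for methylation and 0.167 for both read shares).

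Methylation was higher in PC9 at 568 TE copies and lower at 30 of the 715 tested by limma. Gypsy copies made up most of these: 463 rose, 22 fell and 78 did not pass among 563. Among 84 Copia copies 62 rose and 4 fell, and among 23 LINE copies 16 rose and 1 fell. The short copy Gypsy_49 on scaffold 9 (1151432 to 1151492) stood at 99.3% ± 1.15 in PC9 and 1.0% ± 1.73 in PC15 (limma adjusted p = 3.79e-08). Gypsy_20 on scaffold 10 (279642 to 282321) went the other way, with 0.585% ± 0.202 in PC9 and 62.1% ± 0.375 in PC15 (limma adjusted p = 2.06e-14). The same Gypsy_20 copy had 71.7 ± 38.02 mRNA RPM in PC9 and 0.0264 ± 0.0231 in PC15 (edgeR adjusted p = 6.09e-13).

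The Copia_5 family had 2940.2 ± 441 RPM in PC15 and 0.527 ± 0.290 in PC9, and the Gypsy_1 family 2103 ± 659 and 2.67 ± 0.509. The Copia_5 copy on scaffold 1 (983144 to 983744) fell by 12.19 on the log2 scale (SE 1.25, edgeR adjusted p = 9.49e-09). The nested copies Gypsy_2 (2721841 to 2734474) and Gypsy_22 (2723429 to 2732982) on scaffold 7 overlap and share reads. With no read in PC9, they were at least 1844-fold and 1812-fold lower there than in PC15, against a floor of 3 reads over the group. Whether these copies are present in PC9 was not tested. With TMM scaling inside the TE table, edgeR called 82 copies higher and 186 lower in PC9 of 314 tested. Scaled by library totals, 16 were higher and 362 lower of 428, and the median copy shifted by -3.73 on the log2 scale between the scalings. Relative to other TE copies, Gypsy went down (158 fell and 51 rose of 238) and LINE went up (13 rose and 5 fell of 24). Camera gave an adjusted p of 0.000558 for each of these classes, and an adjusted p = 0.0942 with an estimated correlation. With library totals 3 LINE copies were higher and 14 lower. The LINE median was then -2.21 on the log2 scale against -7.67 for Gypsy, so LINE stood above Gypsy under both scalings while most LINE copies were lower in PC9.

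Small RNA differed between PC9 and PC15 at 340 of 608 TE copies by edgeR. Gypsy_2 copies held 249250 ± 25157 small RNA RPM in PC15 and 3963 ± 6018 in PC9. TIR1 copies held 156 ± 92.1 in PC15 and 58469 ± 54280 in PC9. All 10 TIR copies rose in PC9 by edgeR under both scalings. Camera gave this class an adjusted p of 2.83e-07, and an adjusted p = 0.149 with an estimated correlation. The TIR1 copy on scaffold 2 (1605772 to 1609503) rose by 12.37 on the log2 scale (SE 1.22, edgeR adjusted p = 7.31e-07). DESeq2 gave no adjusted p for this copy. HELPO2 on scaffold 6 (1795682 to 1796094) held 12052 ± 645 RPM in PC15 and 0.348 ± 0.603 in PC9. Of the 340 copies, 231 were higher and 109 lower in PC9. Scaled by library totals, 104 were higher and 185 lower of 633, with a median shift of -2.10 on the log2 scale.

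Gene mRNA differed widely between the strains. By limma, 1764 genes were higher and 3347 lower in PC9 of 10928 tested. Genes with a methylation value numbered 11142 in PC9 and 11650 in PC15. Among genes over 5 kb from a TE copy, 456 lacked a value in some library. Of these, 98.5% ± 0.439 had an RPKM under 1 in PC9 and 58.3% ± 1.66 in PC15. Some of the lower calls may therefore be genes missing or poorly matched in PC9. Gene 1098459 had an RPKM of 777 ± 137 in PC9 and 0.222 ± 0.252 in PC15, and gene 162504 had 0.115 ± 0.1998 and 561 ± 35.3. Methylation was higher in PC9 at 721 genes and lower at 285 of 11140 by limma, and 549 of the former rose by over 10 points. Gene small RNA was higher at 958 genes and lower at 1016 of 6670 by edgeR. With library totals it was higher at 950 and lower at 498.

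The comparison of HyB with its parents asks what mating does to TE silencing. HyB lay between PC15 and PC9 in TE methylation and TE mRNA. Mean TE methylation was 28.5% ± 0.659, above every PC15 library and below every PC9 library. TE mRNA was 3412 ± 55.1 RPM, above every PC9 library and below every PC15 library. The TE share of small RNA was 61.9% ± 6.36, near that of PC15. Against the mean of both parents, the exact two-sided permutation test gave p = 0.464 for methylation, 0.440 for the TE share of mRNA and 0.333 for the TE share of small RNA (n = 3 and 6). This test takes the 6 parental libraries as 1 group, so with HyB between the strains it cannot give a small p. Mean TE methylation in HyB was 7.12 points below the parental mean of 35.7%, so HyB was closer to PC15 in methylation. Total TE mRNA was below the parental mean of 8470.7 RPM, so the HyB total was closer to that of PC9. Single families differed in this. HELPO1, the family with most mRNA in PC9, held 1366.1 ± 68.8 RPM there, 128.01 ± 66.1 in PC15 and 125.65 ± 71.7 in HyB. Copia_5 and Gypsy_1 had the most mRNA in PC15, and held 8.95 ± 9.89 and 21.46 ± 10.3 RPM in HyB. HyB thus lay near PC15 for HELPO1 and near PC9 for Copia_5 and Gypsy_1.

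Methylation in HyB was lower than the parental mean at 396 TE copies and higher at 57 of 715 by limma. Gypsy copies accounted for 339 of those that fell. Gypsy_1 on scaffold 1 (976464 to 983142) stood at 18.1% ± 5.42 in HyB, 25.6% ± 2.63 in PC15 and 85.1% ± 1.89 in PC9. Gypsy_27 on scaffold 7 (1197629 to 1197696) stood at 68.2% ± 10.6 in HyB, 35.6% ± 3.30 in PC15 and 22.7% ± 7.77 in PC9 (limma adjusted p = 3.62e-06). TE mRNA was higher in HyB than the mean of parental log values at 103 copies and lower at 43 of 314 by edgeR. With library totals, 76 were higher and 69 lower, with a median shift of -0.56 on the log2 scale. With the nearly identical HyB replicates 2 and 3 and the like pair of primordia each merged, 114 were higher and 24 lower. Copia_7 on scaffold 2 (2182130 to 2187456) was called higher on that scale, yet held 233 ± 47.7 RPM in PC15, 106 ± 27.6 in HyB and 0.0135 ± 0.0233 in PC9. Copia_6 on scaffold 2 (2175989 to 2181435) was above both parents, with 4.202 ± 2.74 in HyB, 0.326 ± 0.192 in PC15 and 0.0135 ± 0.0233 in PC9.

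Small RNA was higher in HyB than the mean of parental log values at 133 TE copies and lower at 17 of 608 by edgeR, and at 197 and 9 of 633 with library totals. Without PC9 replicate 1 the count of 150 became 252. All 10 TIR copies were higher on that scale under both scalings. The TIR1 copy with most reads, on scaffold 2 (1605772 to 1609503), held 42802 ± 26930.0 RPM in HyB, 55051 ± 50821 in PC9 and 61.6 ± 88.6 in PC15, and the HyB libraries overlapped those of PC9. Camera gave TIR an adjusted p of 3.78e-07, and an adjusted p = 0.222 with an estimated correlation. Gypsy_5 on scaffold 4 (1038235 to 1044128) held 25965 ± 13098 small RNA RPM in HyB, 3221 ± 1007 in PC15 and 8.22 ± 12.5 in PC9. Copia_5 on scaffold 7 (153231 to 159810) was called lower than the mean of parental log values. It held 122 ± 77.3 RPM in HyB, 25424 ± 15492 in PC15 and 156 ± 112 in PC9, and the HyB libraries overlapped those of PC9. Genes changed in both directions. By limma, mRNA was higher at 2214 and lower at 2191 of 10928 genes, which became 1700 and 1316 with the nearly identical libraries merged. Methylation was higher at 243 and lower at 357 of 11140. Gene 31568 had an RPKM of 1041 ± 747 in HyB, 1.32 ± 0.168 in PC15 and 5.01 ± 5.83 in PC9. By edgeR, gene small RNA was higher than the mean of parental log values at 1047 and lower at 474 of 6670 genes. With library totals it was higher at 786 and lower at 307. Where the parents differ, a HyB level at their plain mean lies above the mean of their log values. Calls of higher mRNA or small RNA in HyB, for TE copies and genes, therefore need not reflect an effect of mating.

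The comparison of the N001 mycelium with HyB sets side by side dikaryons that both carry the N001 name. HyB is labelled N001_HyB and was made by mating PC9 with PC15. TE copies were more methylated in N001 mycelium, with 49.1% ± 0.787 against 28.5% ± 0.659 in HyB. TE mRNA was lower, at 2036 ± 203 against 3412 ± 55.1 RPM. The TE share of small RNA was 30.3% ± 0.629 against 61.9% ± 6.36. The libraries did not overlap in any of these measures. The exact permutation test gave p = 0.1 for each, the smallest that 3 against 3 libraries allow (adjusted p = 0.25 for methylation and 0.167 for both read shares).

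Methylation was higher in N001 mycelium at 550 TE copies and lower at 22 of 715 by limma. Gypsy copies rose in 451 cases and fell in 16 of 563, and Copia copies rose in 60 and fell in 3 of 84. Gypsy_7 on scaffold 1 (3222250 to 3227909) stood at 80.6% ± 0.590 in N001 mycelium, 16.2% ± 5.16 in HyB, 35.1% ± 1.30 in PC15 and 62.8% ± 2.92 in PC9 (limma adjusted p = 5.60e-12). Gypsy_27 on scaffold 10 (1313195 to 1313273) went the other way, from 72.2% ± 4.86 in HyB to 4.0% ± 4.58 in N001 mycelium (limma adjusted p = 4.28e-10). At the 245 copies with no methylation value in PC9, N001 mycelium stood at 45.6% ± 1.16, HyB at 26.7% ± 1.12 and PC15 at 25.4% ± 0.646.

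TE mRNA was higher in N001 mycelium at 31 copies and lower at 115 of 314 by edgeR. With library totals, 7 were higher and 162 lower of 428, with a median shift of -0.92 on the log2 scale. With the nearly identical libraries merged, 14 were higher and 121 lower. Gypsy_5 on scaffold 1 (4115924 to 4122899) had no read in N001 mycelium and 42.7 ± 11.5 RPM in HyB (edgeR adjusted p = 4.31e-09). Copia_14 on scaffold 6 (2651076 to 2653516) rose from 0.308 ± 0.0423 to 24.2 ± 7.52 (edgeR adjusted p = 1.35e-09). Relative to other TE copies, Gypsy went down (94 fell and 16 rose) and LINE went up (8 rose and 2 fell of 24). Camera gave adjusted p values of 0.00197 and 7.12e-05, and an adjusted p = 0.0862 for both with an estimated correlation. With library totals, 3 LINE copies rose and 3 fell, with a median of 0.07 on the log2 scale against -2.10 for Gypsy.

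Small RNA was higher in N001 mycelium at 88 TE copies and lower at 89 of 608 by edgeR. With library totals, 7 were higher and 94 lower of 633, with a median shift of -1.09 on the log2 scale. The count of 177 fell to between 60 and 153 when any 1 of the 6 libraries was left out, with fewer libraries to test. It was 74 without HyB replicate 1, 109 without HyB replicate 2 and 106 without HyB replicate 3. It was 60 without N001 mycelium replicate 2 and 68 without replicate 3. Gypsy_2 on scaffold 7 (1795447 to 1798309) had no small RNA read in N001 mycelium and 899 ± 609 RPM in HyB (edgeR adjusted p = 0.00444). Gypsy_3 on scaffold 7 (3040410 to 3050430) fell from 12969 ± 10196 in HyB to 21.4 ± 2.82 (edgeR adjusted p = 0.00103).

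Gene methylation was higher in N001 mycelium at 655 genes and lower at 183 of 11140 by limma, and 477 of the former rose by over 10 points. Gene mRNA was higher at 395 and lower at 816 of 10928. With the nearly identical libraries merged, 305 genes were higher and 669 lower. With replicate 1 of every group left out, 1118 were higher and 1245 lower. That setting leaves HyB with its nearly identical pair, so the spread may be set too low and these counts too high. Gene 152365 fell from an RPKM of 199 ± 7.45 in HyB to 0.0516 ± 0.0894 in N001 mycelium, and gene 1090179 rose from 42.4 ± 38.02 to 7421 ± 6879. Gene small RNA was higher at 92 and lower at 210 of 6670 by edgeR, which became 260 and 97 with library totals. This count of 302 was 186 without HyB replicate 1 and 180, 155 and 139 without N001 mycelium replicates 1, 2 and 3.

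**Figure D2:**
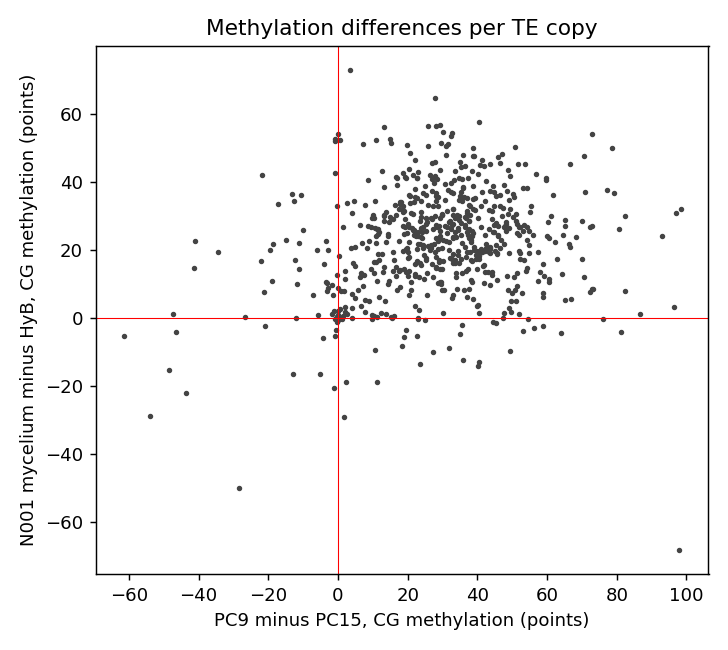
Methylation differences of 715 TE copies, each a point, as PC9 minus PC15 (points of CG methylation, horizontal) and N001 mycelium minus HyB (points, vertical). Most points lie above 0 on both axes: 498 copies passed the test as higher in both comparisons.

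The comparison of primordium with mycelium of N001 asks whether TE silencing changes when fruiting starts. TE methylation hardly differed, with 50.9% ± 1.89 (n = 2) in primordia and 49.1% ± 0.787 in mycelium, and these libraries overlapped (exact permutation p = 0.2, adjusted p = 0.333). TE mRNA was 1244 ± 140 RPM in primordia and 2036 ± 203 in mycelium. The TE share of small RNA was 36.8% ± 4.74 in primordia and 30.3% ± 0.629 in mycelium. The libraries did not overlap in the latter measures (exact permutation p = 0.1, the smallest possible, adjusted p = 0.167).

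Gypsy_27 on scaffold 4 (316146 to 317031) fell from 16.6 ± 10.3 mRNA RPM in mycelium to 1.27 ± 0.365 in primordia (edgeR adjusted p = 0.000837). Copia_7 on scaffold 8 (325976 to 331023) fell from 3.32 ± 1.39 to 0.0779 ± 0.1002 (edgeR adjusted p = 8.86e-05). The LINE_1 family held 773 ± 124 mRNA RPM in mycelium and 234 ± 35.6 in primordia. This family thus made most of the drop in total TE mRNA. The median TE copy changed by 0 on the log2 scale under both scalings. Over all TE copies, edgeR called 2 higher and 7 lower in primordia of 314. This count of 9 was 14 without mycelium replicate 1, 3 without mycelium replicate 3 and 5 without primordium replicate 2. Copia_12 on scaffold 2 (2081708 to 2081837) was the single TE copy called for methylation, with 23.1% ± 1.03 (n = 2) in primordia and 18.4% ± 1.16 in mycelium (limma adjusted p = 0.00438). This call was lost on the logit scale and among copies with a mean level of at least 1%. It was also lost without primordium replicate 2, a setting that leaves 1 primordium library, assumed to vary like the other groups, and so has little weight. No gene passed for methylation by limma (467 at an unadjusted p under 0.05), although 2 passed without primordium replicate 2, with the same limit. No TE copy passed for small RNA by edgeR (54 at an unadjusted p under 0.05), against 2 by DESeq2 and 1 by edgeR without mycelium replicate 1. With replicate 1 of every group left out, 21 copies were higher and 29 lower.

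Gene mRNA was tested at the same step: 1729 genes were higher and 2382 lower in primordia of 10928 by limma. Gene 1100161 rose from an RPKM of 33.7 ± 24.9 to 8431 ± 4132, and gene 199491 fell from 7805 ± 3098 to 2.28 ± 1.74. Primordium replicates 2 and 3 were nearly identical in mRNA. With this pair and the like pair of HyB each merged, 1171 genes were higher and 1699 lower. Gene small RNA was higher at 252 and lower at 185 genes by edgeR, which became 146 and 333 with library totals. This count of 437 was 167 and 135 without mycelium replicates 2 and 3, and 267, 146 and 151 without primordium replicates 1, 2 and 3.

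The comparison of fruitbody with primordium follows TE silencing to the end of fruiting. TE levels hardly differed: mean TE methylation was 50.03% ± 0.763 in fruitbodies, TE mRNA 1203 ± 114 RPM, and the TE share of small RNA 37.8% ± 2.45. The libraries of the 2 stages overlapped in each measure (exact permutation p = 0.7 for methylation, 0.7 for the mRNA share and 0.8 for the small RNA share; adjusted p = 0.7, 0.7 and 0.8). Copia_12 on scaffold 2 (2081708 to 2081837) stood at 18.02% ± 0.729 methylation in fruitbodies (limma adjusted p = 0.00213). This call was lost on the logit scale and among copies with a mean level of at least 1%, and it rests on the same 2 primordium libraries as the call against mycelium. It was the single TE call of 715, against 3 calls without fruitbody replicate 1, 2 without fruitbody replicate 2 and 2 without primordium replicate 2. The last setting leaves 1 primordium library, assumed to vary like the other groups. No TE copy passed for mRNA (14 at an unadjusted p under 0.05) or small RNA (17) by edgeR, and DESeq2 called 0 and 1. With replicate 1 of every group left out, edgeR called 7 and 2. No gene passed for methylation by limma (392 at an unadjusted p under 0.05), against 2 without primordium replicate 2, again with 1 primordium library.

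Gene mRNA was higher in fruitbodies at 5 genes and lower at 25 of 10928 by limma, with 945 at an unadjusted p under 0.05. Gene 1092036 rose from an RPKM of 83.2 ± 40.7 to 491 ± 191 (limma adjusted p = 0.00941), and gene 1114418 fell from 207 ± 57.5 to 28.05 ± 26.4 (limma adjusted p = 0.0178). The count of 30 was 0 without fruitbody replicate 1, 144 without fruitbody replicate 2 and 7 without fruitbody replicate 3. It was 8 and 7 without primordium replicates 2 and 3, and 4 with the nearly identical libraries merged. It was 54 with the replicate number as a block, 98 with replicate 1 as a batch and 582 with replicate 1 of every group left out. The last of these settings leaves primordia with their nearly identical pair, so the count of 582 may be too high. Gene small RNA was lower at 5 genes by edgeR. This count was 2 without any 1 of the fruitbody replicates or primordium replicate 1, and 3 without primordium replicate 3.

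Across TE copies, methylation and mRNA went in opposite directions. Spearman's rho was -0.20 in PC9, -0.16 in HyB, -0.16 in N001 mycelium, -0.19 in primordia and -0.19 in fruitbodies. Each of these had a permutation p of 1e-05, the smallest that 100000 permutations can give (adjusted p = 1.2e-05). Pearson's r was -0.27, -0.13, -0.25, -0.27 and -0.26 for the same groups. In PC15 rho was -0.02 (permutation p = 0.46, adjusted p = 0.46) and r was -0.06, but per kb of copy rho was -0.15 in PC15 (adjusted p = 2.2e-05). Small RNA and mRNA of TE copies rose together, with rho from 0.20 in primordia to 0.61 in PC15 (permutation p = 1e-05, adjusted p = 1.2e-05). Per kb of copy this relation was 0.29 in PC15 and between -0.07 and 0.03 in the other groups. Methylation and small RNA had rho between 0.10 in PC9 and 0.23 in fruitbodies, with adjusted p of 0.0048 and 1.2e-05. Per kb of copy this relation was lost in PC9 (rho -0.01) and N001 mycelium (rho 0.01), with an adjusted p of 0.71 for both. These 18 correlations are across TE copies, which are not independent replicates. TE copies methylated over 50% took 12.2% ± 1.85 of TE mRNA reads and 81.1% ± 5.09 of TE small RNA reads in N001 mycelium, where they were 571 of 973 copies. Their median small RNA was 12.4 ± 1.59 RPM there, against 11.3 ± 0.606 for copies at 10% to 50%. The read share thus rests on copies with many reads and not on the typical copy. In PC15 copies methylated over 50% were 56 of 977 and took 2.52% ± 0.218 of TE small RNA reads, and in HyB they were 115 of 972 and took 10.3% ± 5.52. Copies methylated at 10% to 50% took 95.6% ± 0.0792 in PC15 and 88.6% ± 5.87 in HyB, where they were 652 of 977 and 666 of 972 copies.

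Genes close to TE copies were more methylated and more often silent. Of 433 genes within 1 kb of a TE copy, 52.3% ± 1.31 had an RPKM under 1 in PC9, 34.6% ± 1.29 in PC15, 42.8% ± 0.874 in HyB and 49.5% ± 0.667 in N001 mycelium. Of 10429 genes over 5 kb away, 14.8% ± 0.140 did so in PC9, 8.34% ± 1.06 in PC15, 9.42% ± 0.523 in HyB and 10.4% ± 1.01 in N001 mycelium. Genes with a methylation value numbered 11142 in PC9 and 11648 to 11651 in the other groups, so some genes could be missing in PC9 and count as silent. Among the 349 genes within 1 kb with a value in every library, the share was 41.0% ± 1.60 in PC9, 28.5% ± 1.44 in PC15, 34.9% ± 0.921 in HyB and 39.4% ± 0.827 in N001 mycelium. Among 9973 such genes over 5 kb away it was 10.9% ± 0.135, 6.06% ± 1.04, 6.63% ± 0.471 and 7.19% ± 1.01, so the relation to distance stayed while the levels fell. Mean methylation of the 349 genes within 1 kb was 21.7% ± 0.273 in PC9, 9.52% ± 0.160 in PC15, 14.4% ± 0.447 in HyB and 23.5% ± 0.449 in N001 mycelium. Genes methylated over 50% numbered 63 in PC15, 421 in PC9, 178 in HyB, 701 in N001 mycelium, 732 in primordia and 715 in fruitbodies. Between 94.9% ± 0.562 (HyB) and 97.4% ± 0.238 (PC9) of these genes had an RPKM under 1. Among genes methylated under 10%, the share was 5.44% ± 1.12 in PC15 and 8.99% ± 0.233 in PC9, the lowest and highest of the 6 groups.

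**Figure D3:**
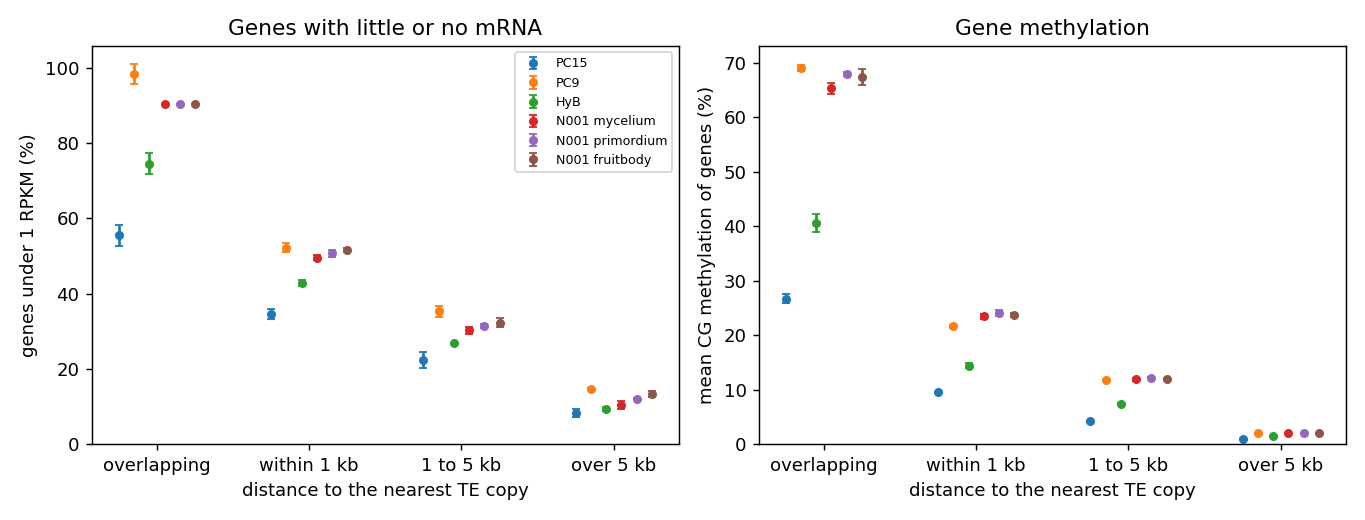
Genes by distance to the nearest TE copy (overlapping, within 1 kb, 1 to 5 kb, over 5 kb) in the 6 groups: share of genes with an RPKM under 1 (percent, left) and mean CG methylation (percent, right); points are group means and bars SD over libraries. Both measures fall with distance in each group, from 98.4% to 14.8% of genes under an RPKM of 1 in PC9.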

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

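Tests with replicate 1 left out or as a batch, nearly identical libraries merged, library totals, recovered reads, copies of at least 200 bp, every copy with a value, levels per kb of copy and genes with a methylation value in every library were chosen after the results were seen. Of the results that answer a comparison, 432 values kept their direction and side of the threshold, lay within 1.5 times the reported count, or moved by less than 1 SD between replicates. Beyond that, 90 moved, 10 reversed, 2 were no longer past the threshold and 1 newly passed it. Of the values of single named features, 1002 did so, 47 were no longer past the threshold and 0 reversed. Where no cause is given, the cause was not tested.

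Leaving out replicate 1 of every group changed these counts, with fewer samples: mRNA genes 2363 (N001 mycelium against HyB), 6505 (primordium against mycelium) and 582 (fruitbody against primordium, 27 of them among the reported 30); TE mRNA 46 and 7 at the latter steps; gene small RNA 2381 (HyB against monokaryons), 790, 1110 and 226; TE small RNA 266 (HyB), 50 (primordium) and 2 (fruitbody). In mRNA, leaving out replicate 1 keeps only the nearly identical pairs of HyB and primordia. The spread may then be set too low and the mRNA counts too high. With replicate 1 as a batch, the counts were 98 (mRNA genes, fruitbody), 16 (TE mRNA, primordium) and 12 (gene small RNA, fruitbody). DESeq2 gave 20 for TE mRNA (primordium), 13 for gene small RNA (fruitbody), and 2 and 1 for TE small RNA (primordium and fruitbody). With no filter, TE mRNA gave 412 (PC9 against PC15, more copies tested) and TE small RNA 117 (N001 mycelium against HyB), and library totals gave 101 for the latter. mRNA genes of fruitbody against primordium numbered 10 with quantile normalization and 4 with merged libraries. Both single calls of TE methylation became 0 on the logit scale, with a mean level of at least 1% and with copies of at least 200 bp, which leave out that copy of under 200 bp.

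Leaving out each library in turn gave 0 to 144 mRNA genes (fruitbody), 3 to 14 TE copies for mRNA (primordium), 139 to 257, 135 to 419 and 2 to 4 genes for small RNA (N001 mycelium, primordium, fruitbody), 132 to 252, 60 to 153 and 0 to 1 TE copies for small RNA (HyB, N001 mycelium, primordium), 0 to 2 genes for methylation at both fruiting steps, and 0 to 1 and 1 to 3 TE copies for methylation (primordium, fruitbody). Differences between fruitbody and primordium in TE summaries changed sign: the TE share of mRNA from -0.00476 to 0.0021 without fruitbody replicate 3 and 0.00433 without primordium replicate 1, that of small RNA from 0.966 to -0.0196 without fruitbody replicate 1 and -1.77 without primordium replicate 1, and mean TE methylation from -0.845 to 0.490 without primordium replicate 2. The other ends of these ranges were -0.0116 without fruitbody replicate 2, 2.36 without primordium replicate 3 and -2.18 without primordium replicate 1.

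Mean TE methylation differences moved with the median over copies to 30.1 (PC9 against PC15), -10.1 (HyB) and 26.9 points (N001 mycelium), and with every copy with a value to 26.4 and -7.97 points for PC9 and HyB. The TE share of mRNA in primordia against mycelium moved to -0.0646 points without the top TE. Among genes with a methylation value in every library, the share under an RPKM of 1 fell within 1 kb of a TE copy to 28.5% (PC15), 41.0% (PC9), 34.9% (HyB), 39.4% (N001 mycelium), 41.0% (primordia) and 42.1% (fruitbodies), and over 5 kb away to 6.06%, 10.9%, 6.63%, 7.19%, 8.95% and 10.2%. With limits of 5% and 30%, the share of highly methylated genes under an RPKM of 1 was 73.95% (PC15), 91.0% (PC9), 84.5% (HyB), 90.9% (N001 mycelium), 91.6% (primordia) and 91.9% (fruitbodies). Per kb of copy, rho of small RNA and mRNA became -0.0288 (HyB), -0.0312 (N001 mycelium), -0.0670 (primordia), -0.0639 (fruitbodies) and 0.0252 (PC9), rho of methylation and small RNA -0.0139 (PC9) and 0.0118 (N001 mycelium), and rho of methylation and mRNA in PC15 -0.15, now past the threshold.

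With the replicate number as a block, mRNA genes of fruitbody against primordium numbered 54 instead of 30, and no other count moved by over 1.5 times. Same-numbered mRNA libraries correlated over 0.1 in 32 of 45 pairs (-0.07 to 0.51, median 0.18, against -0.10 for other numbers), and 12 of 18 lay closest to a library of their own number. For TE small RNA, 13 of 18 libraries lay closest to their own number, though 5 of 45 pairs correlated over 0.1. In TE methylation 8 of 40 pairs did so, at up to 0.68, and in gene methylation 11 of 40, at up to 0.66. A shared effect of the replicate number is therefore open for mRNA and not excluded for the other assays. The rule that all pairs correlate was not met, and no block was used. A pseudocount does not apply to the count tests, and a coverage minimum for methylation could not be tried, since coverage is unknown. Depth limits small RNA in fruitbody replicate 2, with 191411 reads.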

Other observations

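Tests of the shared copies, of HyB as a mixture, of the source of small RNA in PC9 replicate 1, and of other splits of the libraries were chosen after the results were seen.

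TIR1 copies held little small RNA in PC15 and much in every other group. The level was 156 ± 92.1 RPM in PC15, 58469 ± 54280 in PC9, 55370 ± 35221 in HyB, 120430 ± 12094 in N001 mycelium, 162110 ± 33186 in primordia and 152380 ± 17936 in fruitbodies. The PC9 libraries varied widely, as the SD shows. TIR1 methylation was 36.0% ± 2.48 in PC15, 59.1% ± 2.35 in PC9, 52.4% ± 0.353 in HyB and 63.3% ± 0.837 in N001 mycelium, and TIR1 mRNA was 8.45 ± 2.31 RPM in PC15 and 0.0675 ± 0.0840 in PC9. The Copia_5 family held 62857 ± 21330 small RNA RPM in PC15, 595 ± 335 in HyB and 184 ± 27.3 in N001 mycelium. These families were chosen after their values were seen.

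TE methylation was higher in N001 mycelium than in HyB. Incomplete bisulfite conversion would lift every level, but 10359 genes under 2% in both monokaryons changed by a median of -0.00694 points, against 21.6 points for TE copies. If the 245 copies with no PC9 value were read from the PC15 genome alone, a different share of the parental genomes would leave PC15 levels there. N001 mycelium was 20.2 points above PC15 at them, and its lowest library was 18.3 points above the highest PC15 library. This argues against share alone at those copies. At the 715 copies with values in every library, the fitted weight of PC15 was 0.749 in HyB and 0.224 in N001 mycelium. There, a part of the difference may come from share, which remains open. Short copies did not carry the difference, since the 359 copies of at least 1 kb changed by a median of 25.4 points and the 112 copies under 200 bp by 0.345. These values are consistent with a biological difference between the dikaryons, as a hypothesis found and tested on the same data, while differences in growth or age between the cultures remain untested.

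TE copies had fewer mRNA reads in PC9 than in PC15. Copies with no methylation value in PC9, which could be missing there, do not carry this difference: over the 719 copies with a PC9 methylation value the ratio of PC9 to PC15 was still 0.181, and the highest PC9 library was 0.211 times the lowest PC15 library. Without the 10 copies with most reads in PC15, PC9 held 2140 ± 109 RPM and PC15 7185 ± 1014, a ratio of 0.298. The total in PC15 was 14642 RPM, so these 10 copies made a large part of the difference. A smaller difference stayed without them. Copies that diverged in PC9, and differences in how well its reads matched the genome used, were not tested and remain open, since the build is not given in the sources used here. A methylation value existed for 977 copies in PC15 and 719 in PC9, so the listed copies cover PC15 better. Copies found in PC9 alone could be absent from the list, which would lower the PC9 total.

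PC9 replicate 1 had a TE share of small RNA of 32.3%, above replicates 2 and 3. Small RNA of PC15 or HyB would have to make up 41.5% or 46.1% of that library, and copies typical of those groups reached only 0.0841 (PC15) and 0.0705 (HyB) times the level needed, so an admixture of that size is excluded and a smaller one remains open. An earlier test on the share at copies with no PC9 value gave a difference of -13.7 points between replicate 1 and the mean of replicates 2 and 3. It had assumed a higher share in the source, but PC15 and HyB stood at 1.44% to 5.29% and PC9 replicates 2 and 3 at 24.0% and 22.3%, so its bounds were wrong and it cannot decide. Without the 10 copies with most reads, the TE share of replicate 1 was still 5.09 times the higher of replicates 2 and 3, which argues against a few copies, and no biological explanation was tested.

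Expressed genes that gained methylation from HyB to N001 mycelium tended to have lower mRNA there. Of 477 genes that gained over 10 points, 123 had a mean RPKM of at least 1 over the libraries of both groups. The others were not tested. For the 123 genes the median log2 change was -1.04 relative to other genes. No set among 10000 random ones matched on mean expression had as low a median (lowest -0.219, against -1.10 for the 123 genes). With the real set counted among them, the share was 0.0001, the smallest they can give. This share treats genes as independent and does not measure the spread between libraries. By limma 64 of the 123 genes were lower and 0 were higher. The difference may reflect silencing that goes with methylation, but the order of the changes and a difference in nuclear share between the dikaryons were not tested.

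HyB may hold unequal parts of its parental genomes. At copies with no PC9 value HyB was 1.31 points above PC15, with libraries that overlapped, which suggests that these copies kept their PC15 level. Over copies with values in every library, HyB was fitted by a weight of 0.749 for PC15 (0.739 to 0.760 per library), with a residual SD of 9.49 points. In N001 mycelium the weight was 0.224, and 146 copies lay over 10 points above both monokaryons, against 7 in HyB. A skew of nuclei, of mapping or of methylation at each copy cannot be told apart here.

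The copies that differed between PC9 and PC15 tended to differ between N001 mycelium and HyB, with Spearman's rho of 0.277 and Pearson's r of 0.268 over 715 copies (permutation p = 1e-05 for each, the smallest possible). Copies higher in both numbered 498, against 437 for independent lists. The comparisons share no library. TE copies are not independent replicates, since some are nested or overlap, so these p values and the expected overlap do not measure chance alone. The relation lay between the bounds set for the same copies being involved (over 0.5) and not (under 0.2), so this cannot be told apart.

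For groups of 3 against 3 libraries there are 10 splits, too few for a share under 0.05, and the real split alone gave as many calls (1 of 10) in each case below. For PC9 against PC15 the real and the highest other count were 5111 and 2 (mRNA genes), 268 and 0 (mRNA TEs), 1974 and 4 (small RNA genes), 340 and 0 (small RNA TEs), 1006 and 0 (methylated genes) and 598 and 0 (methylated TEs). For N001 mycelium against HyB they were 1211 and 23, 146 and 0, 302 and 0, 177 and 0, 838 and 2, and 572 and 0, in the same order. For primordium against mycelium they were 4111 and 0 (mRNA genes), 9 and 0 (mRNA TEs) and 437 and 0 (small RNA genes), and for fruitbody against primordium 30 and 4 (mRNA genes) and 5 and 0 (small RNA genes). With real counts of 0, all 10 splits gave as many: mRNA TEs of fruitbody against primordium (highest other 0) and small RNA TEs of primordium against mycelium (highest other 1) and of fruitbody against primordium (highest other 0).

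For HyB against the monokaryons, up to 100 splits of the 9 libraries were drawn. Under 0.05 of the splits, the bar for excluding chance, were as large for mRNA genes (2 of 100, real 4405, highest other 4407), mRNA TEs (2 of 100, 146 and 160), small RNA genes (1 of 50, 1521 and 1476), small RNA TEs (3 of 100, 150 and 223) and methylated genes (2 of 100, 600 and 675). Methylated TEs did not meet that bar (7 of 100, 453 and 590). These splits exchange libraries of strains that differ, so they do not measure chance alone. The highest other splits put all PC15 or all PC9 libraries in the place of HyB for each of these but mRNA TEs, where it held PC15 replicates 1 and 2 and HyB replicate 1. Other splits as large had a whole strain in the place of HyB in 1 of 1 case for mRNA genes, 2 of 2 for small RNA TEs and 1 of 1 for methylated genes, which points to the structure of the strains. This was so in 0 of 1 for mRNA TEs, so whole strains do not account for that split. For methylated TEs it was so in 2 of 6, the highest among them, so whole strains account for only a part of those splits.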
